A study of Mus musculus with 9 samples.

How the data were processed

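RNA was measured in 9 libraries of mouse kidney cortex: 5 tumour areas from mice with floxed Vhl and Pbrm1 and Ksp-Cre, and 4 areas from wild-type mice. Per the labels, RNA was extracted with a column kit, treated with DNase, selected for poly(A) and made into TruSeq libraries, which were read as paired ends on a HiSeq 2500, and the stated depth is several times the counted reads. The submitters' processing notes name STAR 2.3, HTSeq, edgeR and the genome build mm9. The gene annotation, the strand setting and any filter on the table are not given in the sources used here. The kit is not strand-specific, so reads of overlapping antisense genes cannot be told apart. The deposited table holds raw read counts per gene, 1 column per library, and its values were checked to be whole numbers with 9 different column totals. It has 14052 genes, of which 14026 identifiers matched a mouse symbol and 26 did not. No replicates were pooled, and no column lacked a sample. Counted reads per library ran from 5143527 to 8250261, and 3 counts, the limit that a 0 allows, come to 0.409 to 0.649 CPM.

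The fit used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), which left 7020. Libraries were scaled by TMM, with factors of 1.04 to 1.17 in tumour and 0.89 to 0.90 in normal areas. A quasi-likelihood model with the group as its only term was tested, and Benjamini-Hochberg adjusted p under 0.05 counted as a call, with an absolute log2 fold change of at least 1 as a second count. The common biological coefficient of variation was 0.152. CPM are edgeR values with the TMM factors. With so few libraries, edgeR p-values come from a model fitted across all genes. No coordinates are given, since a later annotation served only for symbols and transcript structure.

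Gene lists, tests, alternatives and the rule for named genes were chosen before the data were examined. The 39 lists cover metabolic and stress programs, cell types of the kidney and immune system, tissues that could be mixed in, and checks on sex, strain and handling. Each list was tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the lists, and with an estimated correlation and fry as alternatives. Calls were counted over all genes and also adjusted over the list alone. A list's value in an area is the mean log2 CPM (prior count 2, or 0.5 as an alternative) of its tested members, relative to the normal areas, tested 2-sided by an exact permutation over 126 splits. Lists of which fewer than 2 genes were tested have no set test, namely neutrophil, adrenal gland, skeletal muscle, and Y chromosome and Xist.

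Named genes include, first, the fixed genes Vhl, Pbrm1, Cdh16, Hif1a, Epas1, Arnt, Hif3a, Stat3, Mtor, Setd2, Bap1, Trp53 and Myc. Second come the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a mean of at least 10 CPM in the higher group and no overlap of the groups, without immunoglobulin and T cell receptor segments, predicted genes and identifiers that are not symbols. Then come up to 2 called genes per list in each direction with a mean of at least 1 CPM in the higher group, members needed to state that they did not pass, and members of the sex and strain lists. Other genes were named after their values were seen: Plin2, Higd1a, Ndrg1, Pkm, Slc37a4, Hmgcs1, Ugt2b37, Ss18, Smarca4, Smarcc1, Dnajb1, Kap, Nnt, all genes of the urothelial, fat, clock, heat shock and glucocorticoid lists in the closing section, and those that stood apart there. Of 165 genes followed singly, not all of them named in the text, 159 were called, and 147 of these had no overlap of the groups.

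Alternatives were RLE, upper quartile and library size scaling, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, edgeR's exact test, a robust fit, the area letter as a covariate, only areas with the letter R, and each area left out in turn. A run without tumour areas L4 and R5 was added after the data were seen. The steps were tested on simulated data built from the real libraries: 52.2% of genes changed 1.5-fold, 86.6% changed 2-fold and 95.5% changed 4-fold were called, 10 of 166 calls (6%) were of unchanged genes, and 1 of 1 raised list and 0 of 20 unchanged lists passed the set test. Only 200 genes were changed, and genes were drawn independently of each other. The simulated set test therefore does not check the preset correlation, and the shares found need not hold for the real data. Copies and overlaps of genes were found with BLAST 2.17.0 and bedtools 2.31.1. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not realigned, and no isoform or deleted exon could be measured.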

Results

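Gene expression was measured by RNA sequencing in kidney cortex of mice about 1 year old. The tumour group holds 5 tumour areas, named L4, R2, R3, R4 and R5, from mice with floxed Vhl and Pbrm1 alleles and the Ksp-Cre transgene. Ksp is the promoter of Cdh16, a cadherin of kidney tubule epithelium. The normal group holds 4 areas, named L1, L2, R1 and R2, from wild-type mice. The meaning of the letters is not given. All tumour descriptions carry 1 number and all normal descriptions another, so each group may be 1 animal, and the p-values then describe the spread between areas. The strain also goes with the group: a mixed C57BL/6, BALB/c and 129 background in the tumour mice and C57BL/6 in the normal mice. Counted reads per library ranged from 5143527 to 8250261 over 14052 genes. In the tumour areas the totals were 6171937 (L4), 5367702 (R2), 5246708 (R3), 6645050 (R4) and 5950779 (R5). In the normal areas they were 5143527 (L1), 8250261 (L2), 6748500 (R1) and 5521673 (R2). A total of 3989 genes (28.4%) had no count in any library, among them 102 of 377 genes from families that nearly every cell uses, so a 0 in this table does not show that a gene was silent. For a gene that was counted, a 0 in 1 library allows up to 0.409 to 0.649 CPM (counts scaled to library size), a limit for counting error only.

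The comparison asks which transcripts differ between the Vhl and Pbrm1 tumours and normal kidney. In the tumour areas, genes of immune cells, cell division, inflammation, glycolysis and amino acid supply rose, and genes of the proximal and distal tubule, of intercalated cells, podocytes and fatty acid oxidation fell. These lists passed a set test with a preset correlation and none passed with an estimated correlation (lowest adjusted p = 0.263). Mzb1, a plasma cell gene, rose from 2.92 ± 0.960 (SD, n = 4) to 488 ± 182 CPM (SD, n = 5), and Mki67, a marker of dividing cells, from 3.37 ± 1.04 to 53.7 ± 10.8 CPM. Hk2, the inducible hexokinase, rose from 2.26 ± 0.515 to 48.9 ± 9.69 CPM. Slc34a3, a phosphate carrier of the proximal tubule, fell from 79.2 ± 5.62 to 7.30 ± 3.04 CPM, and Ppara, a regulator of fatty acid oxidation, from 94.1 ± 11.8 to 13.9 ± 3.11 CPM. Plus-or-minus values after a CPM mean are SDs over 5 tumour or 4 normal areas throughout, and those after a log2 fold change (tumour over normal) are standard errors of the edgeR fit.

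Of 7020 tested genes, 2760 were higher and 2476 lower in the tumour areas at an adjusted p under 0.05 in edgeR, together 74.6%. At least 2-fold changes numbered 1217 higher and 883 lower. Higher genes made up 52.7% of the calls, and 68.9% when libraries were scaled by their size alone, a scaling that moved the median fold change by 0.29 on the log2 scale. Changes are given relative to TMM scaling, under which the median log2 fold change was 0.06. The groups did not overlap in 4762 genes (67.8%), against 1.6% by chance if all 9 areas were independent and exchangeable. If each group is 1 animal, that share does not apply, since any difference between the animals parts the groups. Without tumour areas L4 and R5, a choice made after the data were seen because both carried fat and urothelial transcripts, 2687 genes were higher and 2511 lower. The first principal component held 86.3% of the variance and parted the groups, and the second held 5.5%. Correlations of log2 CPM across genes lay at 0.993 to 0.994 between normal areas, 0.962 to 0.991 between tumour areas and 0.839 to 0.913 between the groups.

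**Figure D1:**
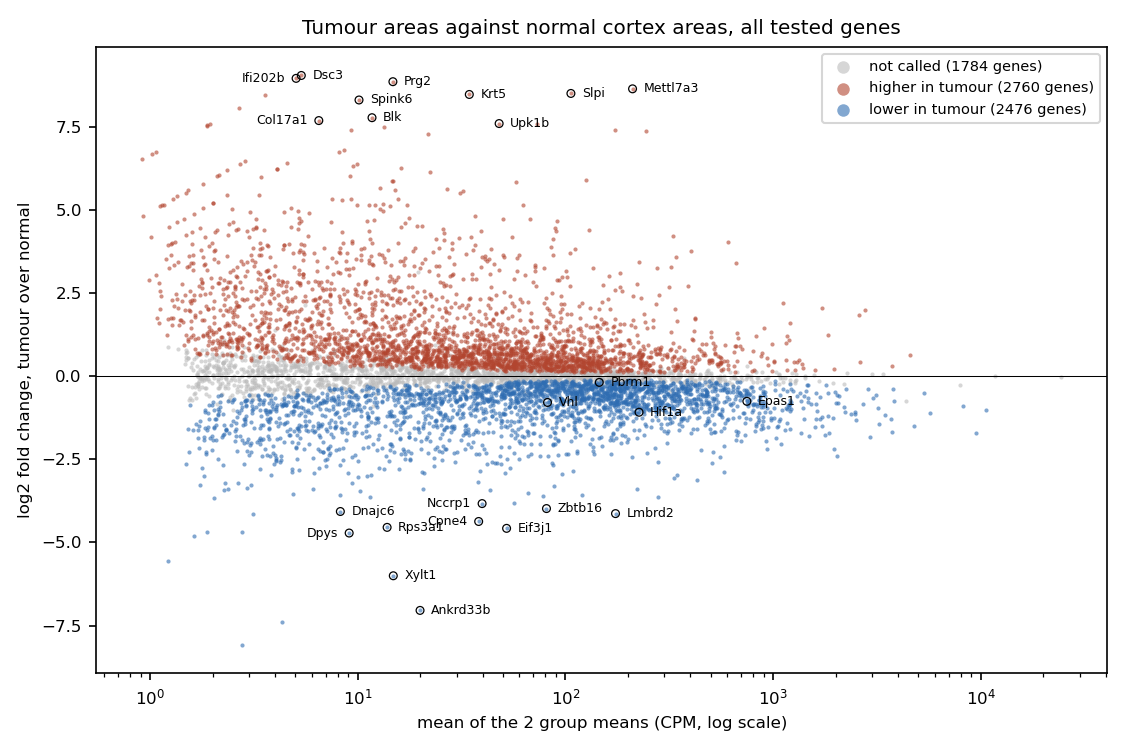
Log2 fold change (tumour over normal) of the 7020 tested genes against the mean of both group means in CPM on a log axis, with genes higher in tumour in red (2760), lower in blue (2476) and the remainder in grey. Named points include Ankrd33b at -7.04, Mettl7a3 at 8.64 and Vhl at -0.79.

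The deleted genes came first. Vhl (ENSMUSG00000033933), whose protein marks HIF alpha subunits for destruction, fell 1.73-fold from a normal mean of 104 ± 4.69 CPM, with a tumour SD of 11.95 CPM (log2 fold change -0.79 ± 0.13, adjusted p = 0.000248 in edgeR). All 5 tumour areas, at 45.1 to 75.7 CPM, lay below all normal areas, at 97.7 to 108 CPM. Pbrm1 (ENSMUSG00000042323), the polybromo subunit of the PBAF chromatin complex, stood at 136 ± 21.5 against 155 ± 10.1 CPM (-0.19 ± 0.11, adjusted p = 0.142). Without tumour L4 the Pbrm1 difference passed the test (-0.25, adjusted p = 0.0336), as it did without L4 and R5 (-0.33). Counts per gene can include exons outside a deleted part and RNA from cells without Cre. Reads shared by several transcripts may also have been left out, as the closing section describes, so the counts may cover only part of each gene. Cdh16 stood at 979 ± 130 against 1147 ± 24.3 CPM (-0.23 ± 0.10, adjusted p = 0.0543), and passed without tumour L4 (adjusted p = 0.041), R3 (0.0435) or R4 (0.0306), with RLE factors (0.0371), with the area letter as a covariate (0.0131), in DESeq2 (0.0277) and in edgeR's exact test (0.049). Over all alternatives the adjusted p ranged from 0.00459 to 0.444 for Pbrm1 and from 0.0131 to 0.499 for Cdh16, and with library size alone both read higher in tumour, at 0.11 and 0.06, without passing.

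Among regulators chosen beforehand, Hif1a and Epas1, which encode the alpha subunits HIF1A and HIF2A, fell (-1.09 ± 0.09, adjusted p = 2.84e-06, and -0.76 ± 0.06, adjusted p = 2.5e-06 in edgeR). Hif1a went from 308 ± 14.5 to 145 ± 19.4 CPM and Epas1 from 940 ± 23.2 to 556 ± 41.5 CPM. Hif3a rose from 15.03 ± 1.58 to 33.7 ± 11.2 CPM (1.16 ± 0.22). Mtor, the kinase of both mTOR complexes, fell from 576 ± 12.6 to 285 ± 51.6 CPM (-1.02 ± 0.12). Setd2, a histone H3 lysine methyltransferase, fell from 183 ± 4.15 to 121 ± 3.01 CPM (-0.60 ± 0.04). Arnt held 13 counts over all libraries, and Stat3 and Bap1 held 0, so none of these was tested. Trp53 and Myc are not among the genes in the table.

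Among genes with a mean of at least 10 CPM and no overlap of the groups, the largest increases included epithelial, immune and protease inhibitor genes. Mettl7a3, of a methyltransferase-like family with close paralogs, rose from 0.910 ± 1.05 to 420 ± 83.5 CPM (8.64 ± 0.36, and 10.01 without normal L2). Slpi, a secreted inhibitor of leukocyte proteases, rose from 0.568 ± 0.160 to 212 ± 88.7 CPM (8.50 ± 0.49). Dsc3, a desmocollin of stratified epithelia, and Ifi202b, an interferon-inducible gene of the strain-dependent list, had no count in the normal areas and were at least 82.8-fold and at least 77.3-fold higher, against a floor of 3 counts over the normal group. Where the normal areas held only 1 or 2 counts, ratios carry 95% counting intervals. The ratio was 691 (124 to 27300) for Prg2, the eosinophil major basic protein, 456 (81.6 to 18000) for Spink6, a serine protease inhibitor, 273 (75.2 to 2260) for Blk, a B cell kinase, and 321 (57.3 to 12700) for Col17a1, a hemidesmosome collagen. The single normal count of Prg2, Spink6 and Col17a1 lay in R1, and without that area the fitted values, which depend on the prior count, moved from 8.85 to 10.50, from 8.30 to 9.95 and from 7.68 to 9.33 on the log2 scale.

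Area L4 carried much of the signal for 3 of these genes. Krt5, a basal keratin, stood at 294 CPM in L4 and 1.89 to 35.8 CPM in the other tumour areas, and its log2 fold change of 8.47 ± 2.36 became 6.00 without L4. Upk1b, a uroplakin of the bladder and ureter lining, stood at 380 CPM in L4 and 3.48 to 66.0 CPM elsewhere (7.59 ± 1.93, 5.63 without tumour L4 and 8.43 without normal L2). Col17a1 moved from 7.68 to 6.04 without L4. Krt5 and Upk1b did not pass in limma-voom.

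The largest decreases were of mixed function. Ankrd33b fell from 39.6 ± 1.06 to 0.280 ± 0.125 CPM (-7.04 ± 0.17), and Xylt1, a xylosyltransferase that starts proteoglycan chains, from 29.2 ± 1.96 to 0.439 ± 0.297 CPM (-6.00 ± 0.30). Dpys, dihydropyrimidinase, fell too (-4.72 ± 0.49, and -5.41 without tumour R4). Zbtb16, a transcription factor induced by glucocorticoids, fell from 153 ± 8.80 to 9.63 ± 1.97 CPM (-3.98 ± 0.12), and Lmbrd2 from 330 ± 24.4 to 18.8 ± 5.65 CPM (-4.13 ± 0.17). Cpne4 (-4.37), Dnajc6 (-4.07) and Nccrp1 (-3.83) fell as well. Eif3j1 (-4.58) and Rps3a1 (-4.55) fell, and both have close copies in the genome, so their counts depend on how shared reads were handled.

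Gene lists were fixed in advance, and 35 held at least 2 tested genes. By camera with a preset correlation of 0.01, 14 lists were higher and 7 lower, each with all 5 tumour areas beyond all normal areas in the mean of its members. With an estimated correlation none passed, and the lowest adjusted p was 0.263, so each value of that kind is given beside its list. By fry, which asks whether members move on balance one way, 31 passed. Of 100 splits of the areas into 5 and 4, 19 gave at least 21 lists past camera, the real split included. Values per area passed an exact permutation test in 30 of 35 lists, at a smallest possible p of 0.00794 over 126 splits. Counts adjusted over the list alone equalled those over all genes in 33 lists and differed in 3, whose counts are given. All p-values of set tests are adjusted over the lists.

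**Figure D2:**
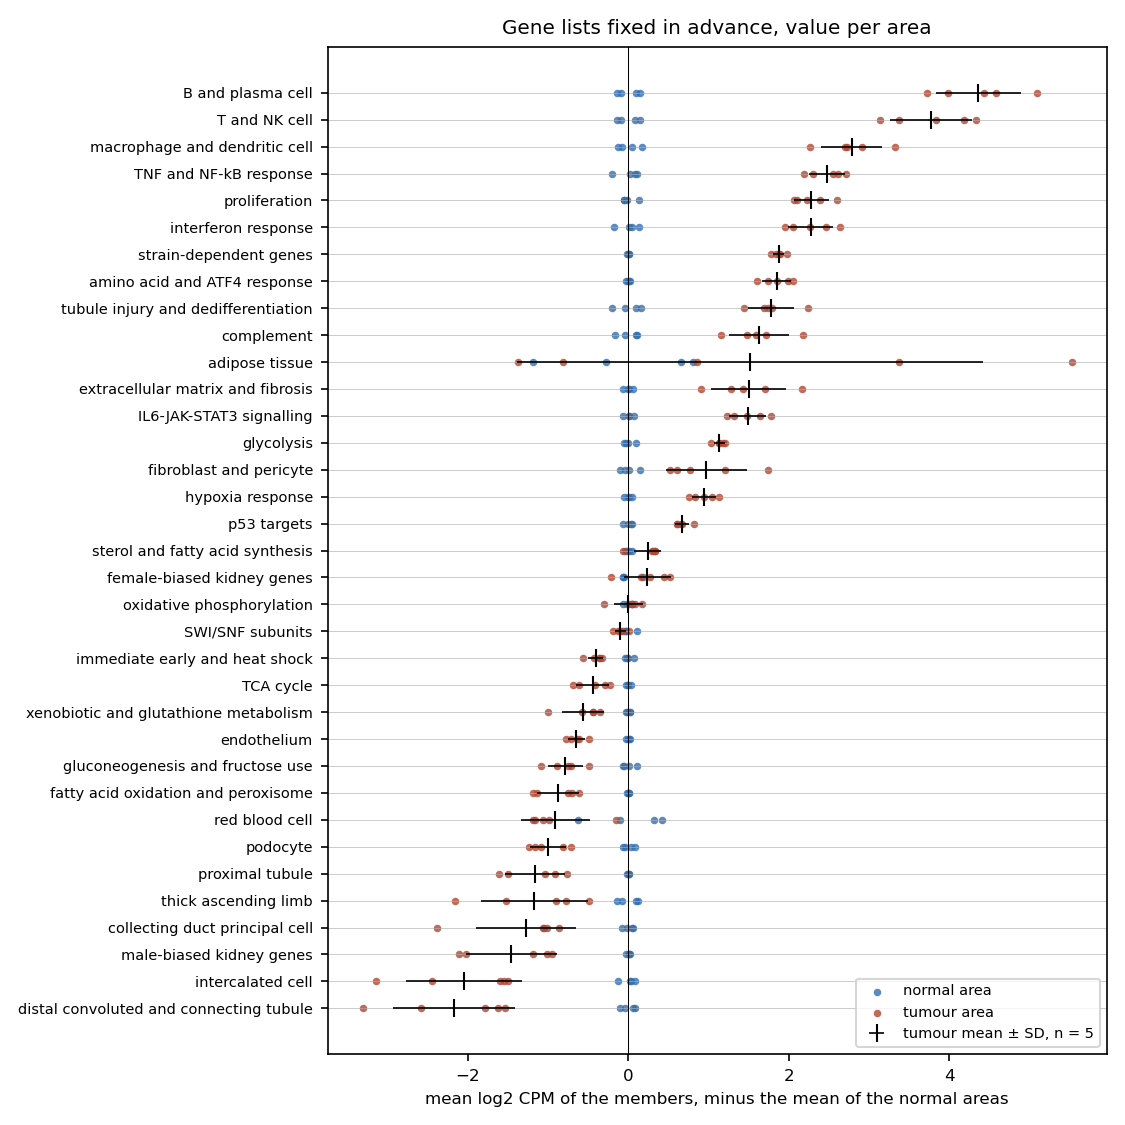
Mean log2 CPM of each list's tested members relative to the normal areas, 1 point per area (normal in blue, tumour in red), with bars for the tumour mean and SD (n = 5). The tumour mean reached 4.36 for B and plasma cell genes and fell to -2.17 for distal convoluted and connecting tubule genes, while adipose genes spread from -1.37 to 5.52 over the tumour areas.

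Immune cell genes had the highest list values. All 9 tested B and plasma cell genes, of 18 fixed and 11 in the table, rose (list value 4.36 ± 0.53 log2, adjusted p = 7.47e-06 by camera, adjusted p = 0.369 with an estimated correlation). Mzb1 rose by 7.36 ± 0.39 and Blk is given above. All 9 tested T and NK cell genes, of 26 fixed and 18 in the table, rose (3.77 ± 0.51, adjusted p = 5.09e-05, adjusted p = 0.369 with an estimated correlation). Among them were the inhibitory receptors Ctla4, from 0.222 ± 0.0814 to 18.8 ± 6.44 CPM, and Pdcd1, from 0.536 ± 0.481 to 29.7 ± 11.5 CPM (5.58, and 6.44 without normal L2). Of 14 macrophage and dendritic cell genes 13 rose and none fell (2.79 ± 0.38, adjusted p = 1.8e-07, adjusted p = 0.369 with an estimated correlation). Gpnmb, a glycoprotein of phagocytes, rose from 0.607 ± 0.448 to 44.1 ± 12.1 CPM, and Lyz1, a lysozyme, by 4.96 ± 0.85, and 4.21 without tumour L4. No neutrophil gene was tested, although 10 were in the table.

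Inflammatory programs moved with them. All 11 tested TNF and NF-kB response genes, of 23 fixed and 17 in the table, rose (2.47 ± 0.22, adjusted p = 1.8e-07, adjusted p = 0.263 with an estimated correlation). They were led by the cytokine Il1b (5.03 ± 0.30) and the chemokine Cxcl1 (4.02 ± 0.38). All 10 tested interferon response genes, of 25 fixed and 16 in the table, rose (2.27 ± 0.28, adjusted p = 7.57e-05, adjusted p = 0.369 with an estimated correlation). Xaf1 rose from 1.07 ± 0.157 to 52.8 ± 13.1 CPM, and Cxcl9, which draws T cells, from 8.88 ± 3.28 to 111 ± 39.8 CPM. In the IL6-JAK-STAT3 list 17 of 21 genes rose and 2 fell (1.49 ± 0.23, adjusted p = 3.36e-05, adjusted p = 0.369 with an estimated correlation). The hyaluronan receptor Cd44 rose by 4.45 ± 0.31, while the receptors Lifr and Il13ra1 fell by 0.81 and 0.38, the latter not called with library size alone. Of 9 complement genes 8 rose (1.62 ± 0.37, adjusted p = 0.0104, adjusted p = 0.506 with an estimated correlation), with C3 at 162 ± 48.9 against 13.1 ± 2.57 CPM and Cfp at 5.62 ± 1.90 against 0.532 ± 0.412 CPM. Cd55, which restrains complement, fell by 0.70 ± 0.17, and was not called with library size alone.

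Cell division genes rose in all 20 tested members, of 36 fixed and 30 in the table (2.28 ± 0.22, adjusted p = 1.8e-07, adjusted p = 0.369 with an estimated correlation). Bub1, a spindle checkpoint kinase, held 3 counts in the normal areas, for a ratio of 18.3 (6.04 to 90.8), and its fitted value of 3.99 became 5.02 without normal L1. Of 9 tested p53 targets 6 rose and 1 fell, a list that did not pass camera (adjusted p = 0.104) but passed fry (7.33e-05). Bbc3, a BH3 protein of apoptosis, rose by 3.45 ± 0.17, Tnfrsf10b, a death receptor, by 1.04 ± 0.16, and Ccng1 fell by 0.95 on the log2 scale.

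Among 20 tested hypoxia response genes, of 40 fixed and 29 in the table, 13 rose and 4 fell (0.94 ± 0.15, adjusted p = 0.0176 by camera, adjusted p = 0.41 with an estimated correlation). The lactate carrier Slc16a3 was higher by a ratio of 105 (28.8 to 870) over 2 normal counts, and Lox, a collagen crosslinking enzyme, rose from 2.63 ± 0.709 to 31.0 ± 10.5 CPM. The mitochondrial adenylate kinase Ak4 fell from 3204 ± 69.6 to 707 ± 154 CPM and Igfbp3 from 14.9 ± 1.37 to 4.32 ± 0.271 CPM. The lipid droplet gene Plin2 fell by 0.67, and was not called with library size alone. Higd1a fell by 0.19, read 0.10 higher with library size alone, and lost its call without tumour L4, R4 or R5 or normal L1 or R1 (adjusted p = 0.0625 to 0.0866), with upper quartile factors, in edgeR's exact test and in the areas with the letter R alone. Ndrg1 stood at 11840 ± 2008 against 11710 ± 403 CPM (0.02 ± 0.14, adjusted p = 0.922), and passed with library size alone (0.30) and without L4 and R5 (0.17). Car9 is not among the genes in the table.

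Of 9 glycolysis genes 6 rose and 2 fell (1.133 ± 0.068, adjusted p = 0.00415, adjusted p = 0.263 with an estimated correlation). Hk2 rose by 4.42 ± 0.21, and Pfkl, a phosphofructokinase, from 67.1 ± 2.59 to 355 ± 43.0 CPM. Hk1 and Pfkm fell by 0.39 and 0.31, and neither was called with library size alone, nor was Pfkm in the areas with the letter R alone. Pkm stood at 491 ± 114 against 462 ± 16.7 CPM (adjusted p = 0.617). Of 6 genes of gluconeogenesis and fructose use 4 fell and 1 rose, and the list did not pass camera (-0.78 ± 0.22, adjusted p = 0.202, fry 0.000303). Slc2a2, Pcx and Slc37a4 fell by 3.28, 1.36 and 1.16 on the log2 scale, and Pck2, the mitochondrial carboxykinase, rose from 32.8 ± 0.827 to 104 ± 19.7 CPM.

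Fatty acid oxidation and peroxisome genes fell: 10 of 14, or 9 when adjusted over the list alone, with none higher, though with library size alone 8 fell and 2 rose (-0.88 ± 0.26, adjusted p = 0.00592, adjusted p = 0.506 with an estimated correlation). Ppara fell by 2.76 ± 0.15 on the log2 scale. Of 13 citric acid cycle genes 9 fell and none rose, including Pdhb (-1.10 ± 0.08) and Suclg2 (-1.01 ± 0.20), while with library size alone 6 fell and 3 rose. This list missed the camera threshold (-0.45 ± 0.20, adjusted p = 0.0758, fry 0.00281), and passed it without tumour R4 (0.0464), over a range of 0.0464 to 0.135 with 1 area left out. Oxidative phosphorylation genes split: of 28 tested, from 65 fixed and 52 in the table, 5 rose and 5 fell (list value 0.00 ± 0.18, adjusted p = 0.951 by camera). The counts were 4 and 5 when adjusted over the list alone, 17 and 1 with library size alone and 7 and 5 with upper quartile factors. The complex I genes Ndufa1 and Ndufa2 rose by 0.41 ± 0.10 and 0.32 ± 0.06, and Ndufs1 fell by 0.72 ± 0.16. Ndufa4 fell by 0.45 ± 0.13, and was not called with library size alone. The median of this list was 0.02 and its mean 0.00.

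Transcripts of the amino acid and ATF4 response list rose in 8 of 12 genes, against 2 lower (1.85 ± 0.18, adjusted p = 0.00415 by camera, adjusted p = 0.263 with an estimated correlation). Pycr1, of proline synthesis, rose from 0.512 ± 0.297 to 25.1 ± 9.38 CPM, and Slc7a11, the cystine carrier, from 0.416 ± 0.146 to 18.1 ± 4.84 CPM. Vldlr fell by 0.87 ± 0.08, and Psat1, of serine synthesis, by 0.59 ± 0.15, the latter not called with library size alone. Sterol and fatty acid synthesis genes went both ways, 10 of 22 higher and 5 lower, 16 and 4 with library size alone (0.24 ± 0.17, adjusted p = 0.273, fry 0.0155). The desaturase Scd1 rose from 1113 ± 148 to 4416 ± 1562 CPM. Fasn, fatty acid synthase, rose by 1.37 ± 0.45, and by 0.74 without tumour L4, where it stood at 640 CPM. Idi1, Acly and Hmgcs1 fell by 1.78, 1.19 and 0.91 on the log2 scale. Among xenobiotic and glutathione genes 8 of 15 fell and 4 rose (-0.57 ± 0.26, adjusted p = 0.199, fry 0.0019). The glutathione transferase Gsta3 and the dipeptidase Dpep1 fell by 2.50 and 1.49. Cyp24a1, which breaks down vitamin D, and Ugt2b37 rose by 0.98 and 0.62. Gstm1 rose by 0.68 ± 0.28 (adjusted p = 0.0491), a call lost without any 1 area other than tumour R2 (adjusted p = 0.0554 to 0.11), and also with RLE factors, in limma-voom and in the areas with the letter R alone.

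Matrix genes rose, 21 of 27 with none lower (1.498 ± 0.471, adjusted p = 0.00042, adjusted p = 0.506 with an estimated correlation). The list value was highest in L4 (2.17) and lowest in R4 (0.91). The proteoglycan Lum rose by 4.15 ± 0.72, and by 3.48 without tumour L4, and the metalloproteinase Mmp7 by 3.98 ± 0.85, and by 5.16 without normal L2. Tubule injury and dedifferentiation genes rose, 10 of 12, or 11 when adjusted over the list alone (1.78 ± 0.29, adjusted p = 0.00111, adjusted p = 0.263 with an estimated correlation). Havcr1, an injury marker of the proximal tubule, was higher by a ratio of 128 (43.4 to 620) over 3 normal counts. Krt20, a keratin that urothelium also expresses, rose by 3.84 ± 0.74, by 3.13 without tumour L4 and by 4.61 without normal L2.

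Of 26 proximal tubule genes 20 fell and 2 rose (-1.17 ± 0.37, adjusted p = 0.000985, adjusted p = 0.506 with an estimated correlation). Slc34a3 fell by 3.43 ± 0.25 and the lactate carrier Slc5a12 by 3.27 ± 0.35, while the protease Napsa rose from 1090 ± 125 to 2582 ± 603 CPM and the sulphate carrier Slc13a1 by 0.44 ± 0.11. All 8 distal convoluted and connecting tubule genes fell (-2.17 ± 0.76, adjusted p = 0.00617, adjusted p = 0.506 with an estimated correlation), with the sodium-calcium exchanger Slc8a1 down from 143 ± 14.1 to 11.8 ± 5.49 CPM and the kinase Wnk1 from 27.5 ± 2.41 to 3.90 ± 1.61 CPM. Of 10 intercalated cell genes 9 fell (-2.05 ± 0.73, adjusted p = 0.00839, adjusted p = 0.506 with an estimated correlation), among them the ammonia channel Rhcg (-3.22 ± 0.47) and the anion exchanger pendrin, Slc26a4 (-2.61 ± 0.41). In area R2 these 2 lists stood lowest, at -3.31 and -3.15.

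In the thick ascending limb 6 of 9 genes fell and none rose, 5 and 1 with library size alone (-1.17 ± 0.67), but the list did not pass camera (adjusted p = 0.182, fry 0.00873). The cotransporter Slc12a1 fell from 295 ± 38.8 to 73.7 ± 33.4 CPM and Egf from 2754 ± 86.0 to 811 ± 432 CPM. In principal cells 6 of 9 genes fell and 1 rose (-1.28 ± 0.63, adjusted p = 0.207, fry 0.00174), and the list passed camera without tumour R2 (0.0416, over a range of 0.0416 to 0.274 with 1 area left out), whose list value of -2.39 stood apart. Hsd11b2, which inactivates glucocorticoids, fell by 2.57 ± 0.35 and the water channel Aqp3 by 2.13 ± 0.46, and the sialyltransferase St6gal1 rose by 1.36 ± 0.32. Of 8 podocyte genes 6 fell and none rose (-1.01 ± 0.22, adjusted p = 0.00941, adjusted p = 0.436 with an estimated correlation), including nephrin, Nphs1 (-2.63 ± 0.24), and Podxl (-1.27 ± 0.08).

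**Figure D3:**
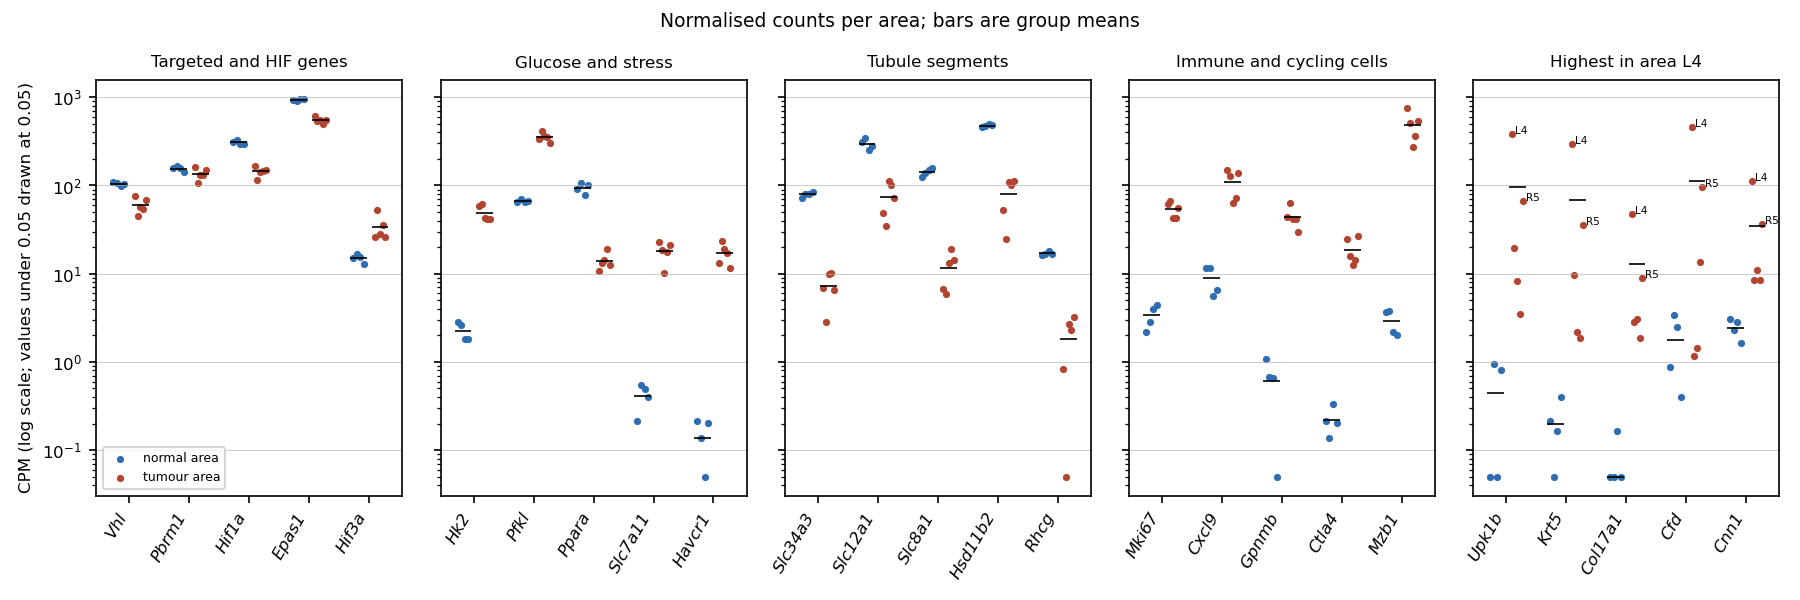
Normalised CPM of 25 named genes in each normal (blue) and tumour (red) area on a log axis, with bars for group means and values under 0.05 drawn at 0.05. Hk2 and Mzb1 stood higher and Slc8a1 and Hsd11b2 lower in all tumour areas, and Upk1b, Krt5, Col17a1, Cfd and Cnn1 were highest in area L4.

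Endothelial genes fell, 7 of 10 against 2 higher (-0.65 ± 0.11, adjusted p = 0.00399, adjusted p = 0.369 with an estimated correlation). The angiopoietin receptor Tek fell by 1.77 ± 0.16 and the phosphatase Ptprb by 1.22 ± 0.06. Esam and Plvap rose by 0.41 ± 0.11 and 0.30 ± 0.09, and lost their calls in the areas with the letter R alone. Of 14 fibroblast and pericyte genes 9 rose and 4 fell, and the list did not pass camera (0.97 ± 0.50, adjusted p = 0.202, fry 0.0243). The list value was highest in L4 (1.73) and R5 (1.21). Cnn1, a contractile protein of smooth muscle, rose by 3.85 ± 0.95, by 2.73 without tumour L4, and did not pass in limma-voom. Thy1 rose from 12.9 ± 1.84 to 130 ± 59.1 CPM, and Pdgfra and Ren1 fell by 1.68 and 1.45 on the log2 scale. Of 13 SWI/SNF subunits other than Pbrm1 itself 7 rose and 5 fell (-0.10 ± 0.07, adjusted p = 0.993), and the list's median of 0.20 and mean of -0.12 differed in sign. The bromodomain gene Brd9 rose by 1.06 ± 0.09 and Smarcd2 by 0.84 ± 0.09, while Bcl7a and Bcl7c fell by 2.25 and 1.72, Ss18 by 0.96, and the ATPase Smarca4 by 0.51. Smarcc1 fell by 0.22 and read 0.07 higher with library size alone.

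Other tissues and possible confounders were also measured. Of 3 adipose genes 1 rose, and the list value spread from -1.37 in R2 to 3.37 in R5 and 5.52 in L4 (1.51 ± 2.90, adjusted p = 0.784). Cfd, adipsin, rose by 5.85 ± 1.84, and by 3.85 without tumour L4, and did not pass without L4 and R5 (1.54), in the areas with the letter R alone (4.19) or in limma-voom (3.58). No adrenal or skeletal muscle gene was tested, although 7 and 10 were in the table. Both tested red blood cell genes fell (-0.91 ± 0.43, adjusted p = 0.584, fry 0.0243). Hbb-bt fell by 1.11 ± 0.29, and Alas2 by 0.77 ± 0.31 (adjusted p = 0.0423), a call lost without any 1 area other than tumour L4 and normal R1 (adjusted p = 0.0618 to 0.161), and also with upper quartile factors, library size alone, the area letter as a covariate, limma-voom and only areas with the letter R. Of 4 immediate early and heat shock genes Nr4a1 rose by 1.75 ± 0.17, and Hsph1, Hsp90aa1 and Dnajb1 fell by 1.55, 1.24 and 0.53 (-0.41 ± 0.10, adjusted p = 0.136, fry 3.91e-06).

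Of 10 male-biased kidney genes 7 fell and none rose, 6 and 1 with library size alone (-1.46 ± 0.57, adjusted p = 0.0296, adjusted p = 0.576 with an estimated correlation), a call lost without tumour L4 (0.0542, over a range of 0.00993 to 0.0542 with 1 area left out). Cyp4a12b and Cyp4a12a, close paralogs, fell by 3.31 and 2.97, while Kap, an androgen-regulated kidney gene, stood at 24070 ± 4912 against 24710 ± 578 CPM (adjusted p = 0.847). Of 6 female-biased genes 2 rose and 1 fell (0.24 ± 0.29, adjusted p = 0.845), with Abcc3 higher by 2.12 ± 0.61, and by 1.38 without tumour L4, Prlr by 1.42 ± 0.27, and Cyp4a14 lower by 1.11 ± 0.36, the last not called in the areas with the letter R alone. The Y-linked Kdm5d stood at 3.68 ± 0.872 against 3.02 ± 0.279 CPM (adjusted p = 0.269) and passed with library size alone (0.56), and Xist is not among the genes in the table. Of 4 strain-dependent genes 3 rose and 1 fell (1.87 ± 0.07, adjusted p = 0.0104, adjusted p = 0.263 with an estimated correlation). Ifi202b is given above, Wdfy1 rose by 2.35 ± 0.09, Nnt by 0.46 ± 0.12, and Glo1 fell by 0.27 ± 0.07 and read 0.02 higher with library size alone.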

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

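Of the tests below, the comparison of urothelial with other lists was chosen only after its result was seen. Areas were compared within each group by the gap between the most extreme area and its neighbour, a rule that chance meets in about 1 of 20 groups. It was met in 32 of 404 groups (7.92%), 21 in tumour and 11 in normal areas, and 15 of these lay in tumour L4.

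Tumour L4 was highest for Krt5 (294 CPM, others 1.89 to 35.8), Upk1b (380, others 3.48 to 66.0), Col17a1 (48.0, others 1.89 to 8.83), Krt20 (33.0, others 4.65 to 10.2), Cnn1 (111, others 8.56 to 36.5), Cfd (456, others 1.18 to 95.9), Fasn (640, others 134 to 246), Lyz1 (26.2, others 4.20 to 9.13) and Abcc3 (17.8, others 3.05 to 5.48). It was also highest for Ptprb (224 CPM), Hbb-bt (33.1), Acaca (6.54), Hpgd (57.8) and the red blood cell list value (-0.16, others -1.20 to -0.99), and lowest for Ndufs8 (102 CPM, others 124 to 132). Tumour R2 was lowest for Cpne4 (1.51 CPM), Arntl (30.7), the sterol and fatty acid synthesis list (-0.064, others 0.29 to 0.34) and the principal cell list (-2.39, others -1.06 to -0.86). Hsp90aa1 was highest in tumour R3 (43.4 CPM) and Cry1 in tumour R4 (4.36 CPM).

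Among normal areas, L1 stood apart for Hk1 (78.1 CPM), Pcx (1450), Xaf1 (1.30), Egf (2880) and the female-biased list (0.18). Area R1 stood apart for C3 (9.30 CPM), Arntl (27.6) and, with 1 count each, Prg2, Spink6 and Col17a1 (0.166 CPM against 0 in the other normal areas). Area L2 stood apart for Ankrd33b (41.2 CPM).

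Many urothelial and fat transcripts stood higher in tumour areas L4 and R5 than in the other tumour areas. Some urothelial genes also lay above all normal areas in all 5 tumour areas. Upk3b stood at 27.2 to 143 CPM against at most 1.91, and Slpi at 118 to 354 CPM against at most 0.68. Spink6, looked up with them, was highest in R3 (31.8 CPM). A lower share of tubule cells would raise the markers of all other cells alike, and stays open for urothelial genes. In 7 of these not looked at before, the median log2 excess in L4 was 2.09 (quartiles 1.27 to 3.64). It lay 0.98 above the next list, fibroblasts and pericytes (1.11, quartiles 0.23 to 1.54). The median excess was 0.79 for B and plasma cells, 0.75 for T and NK cells, 0.61 for macrophages and dendritic cells and 0.18 for endothelium, so the lists did not rise alike. These values rest on area L4 alone, and some of the urothelial genes had few counts, so they do not settle the question for urothelium. The 3 tested adipose genes did not follow the tubule lists. R2 was lowest in the distal and intercalated lists (-3.31 and -3.15) and in the adipose list (-1.37). In the proximal list it stood at -1.50, beside -1.61 in L4. R5 and R3 were near each other in the distal list (-1.63 and -1.79), but not in the adipose list (3.37 and -0.82). For adipose genes these values argue against a lower tubule share as the whole cause. Urothelium mixed into the area is a candidate explanation, since 6 of 7 urothelial genes not looked at before (85.7%) were highest in L4, as were 60.2% of all genes at least 2-fold higher in tumour, so this test separates weakly. The same holds for fat around the kidney, with 6 of 7 such fat genes (85.7%) highest in L4 and R5 against 49.5% of those genes, and with 245 and 263 counts of Ucp1, a brown fat gene, in L4 and R5. A change of the tumour cells themselves in these areas was not tested and stays open, and no sort or gate would have removed other cells.

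Each tissue had a list of genes already looked at and a list of genes held back for the test. The urothelial genes already looked at are the 26 that were looked up once some had been seen among the largest increases. Of 12 tested 11 were called higher, and Gata3 was not (0.52 ± 0.39, adjusted p = 0.252 in edgeR). The 11 include Krt5, Upk1b, Dsc3, Col17a1, Spink6 and Slpi from the largest increases. A call was required for that choice, so the count of 11 is no test. All 3 held back were called higher, but only 2 with RLE factors. Of the fat genes, 1 of 3 already looked at (2 with library size alone) and 2 of 5 held back were called higher and none lower. In the same order, normal cortex expressed, at a mean of at least 1 CPM, 4 of 20 and 3 of 10 urothelial genes in the table, and 3 of 6 and 5 of 9 fat genes. Krt20 is also in the tubule injury list and Cfd in the adipose list.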

How the results depend on the processing

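The run without tumour areas L4 and R5 was chosen only after the data were seen. No paired analysis was possible because the area names do not pair tumour with normal areas. The counts of genes kept their size within 1.5 times in all alternatives: 2425 to 3735 higher, 1689 to 2671 lower, 1041 to 1647 at least 2-fold higher and 608 to 1090 at least 2-fold lower. With library size alone, 4449 of 5236 calls kept their direction, 761 were lost and 26 turned. Of 165 genes followed singly 131 kept their side of the threshold in all alternatives, and those called kept their direction. The direction of genes that were not called was not followed. The other 34 include 28 that lost a call, 4 that gained 1 (Pbrm1, Cdh16, Ndrg1 and Kdm5d) and, with library size alone, 3 that turned: Glo1 to 0.02, Higd1a to 0.10 and Smarcc1 to 0.069, of which Higd1a also lost its call in other alternatives. The shared shift of 0.29 under that scaling shows the cause for these 3. In the simulated data 52.2% of 1.5-fold changes were found, but only 200 genes were changed there. The real fit called 5236 genes, so that share does not show what limits these calls.

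Of 21 lists past camera, 20 passed under all scalings and with any 1 area left out, as well as without L4 and R5 (adjusted p = 2.7e-10 to 0.0415). Set tests were not run with the other filters, tests and covariates. The male-biased list lost its call without tumour L4 (range over areas left out 0.00993 to 0.0542) and without L4 and R5 (0.0819). Lists that passed only in such alternatives were the citric acid cycle (0.0464 to 0.135) and principal cell (0.0416 to 0.274) lists with 1 area left out, and the fibroblast list without L4 and R5 (0.0377). The cause was not tested.

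With an estimated correlation all 21 lost their calls. The adjusted p was 0.263 for glycolysis, ATF4, TNF and NF-kB, tubule injury and strain lists, 0.369 for IL6-JAK-STAT3, proliferation, interferon, endothelium, macrophage, T cell and B cell lists, 0.41 for hypoxia, 0.436 for podocytes, 0.506 for fatty acid oxidation, complement, matrix, proximal tubule, distal tubule and intercalated cells, and 0.576 for male-biased genes. Fry added 10 lists: gluconeogenesis (0.000303), citric acid cycle (0.00281), sterol synthesis (0.0155), p53 targets (7.33e-05), xenobiotic genes (0.0019), thick ascending limb (0.00873), principal cells (0.00174), fibroblasts and red blood cells (both 0.0243) and heat shock (3.91e-06). It asks another question than camera, which compares a list with other genes.

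Other splits of the 9 areas into 5 and 4 were fitted the same way. Of 100 splits only 1, the real one, gave as many genes higher (2760, highest other 1332), lower (2476, highest other 635), at least 2-fold higher (1217, highest other 572) and at least 2-fold lower (883, highest other 236). The other splits mix the groups, so the difference between tumour and normal areas enters their spread and leaves few calls. The counts show that the areas part along the labels, and cannot exclude chance as a source of the difference. If each group is 1 animal, a difference between 2 animals by chance is not excluded. The highest other split was nearly the mirror of the real one, with 1 tumour area beside the normal areas. For the number of lists past camera, 19 of 100 splits gave at least the real 21 (highest other 23, with 4 tumour areas together). No other split is balanced, so each carries part of the difference between tumour and normal areas. The share of 19 in 100 therefore does not measure chance, and chance is not excluded for that number.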

Other observations

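Of the tests below, the spread of clock genes, the single-transcript parts and the overlaps with other genes were chosen only after the results were seen. A list of circadian clock genes was made only after the data were seen and has no set test. Of its 12 tested genes 9 were lower and 2 higher in the tumour areas, where 74.6% of all tested genes were called. Per2, a repressor of the clock, fell from 223 ± 1.43 (SD, n = 4) to 18.6 ± 2.73 CPM (SD, n = 5), Per1 fell by 1.71 ± 0.08 on the log2 scale, and the cryptochromes Cry1 and Cry2 by 2.55 ± 0.18 and 2.38 ± 0.25. Clock, Hlf, Usp2 and Wee1 fell by 1.66, 1.78, 1.66 and 2.27, and Nr1d2 by 0.44. Nr1d1, the nuclear receptor REV-ERB alpha, rose from 14.02 ± 1.84 to 114 ± 9.17 CPM. Arntl, which pairs with Clock, rose by 0.19 ± 0.07 (adjusted p = 0.0389 in edgeR), a call lost without any 1 area other than tumour L4 and R2 (0.0604 to 0.126), and also with RLE factors, with no filter, in DESeq2, in edgeR's exact test and in the areas with the letter R alone.

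Lists of glucocorticoid response, cold-induced and heat shock genes were also made after the data were seen and have no set test. Of 5 tested glucocorticoid response genes 1 was higher, Cdkn1a by 0.93 ± 0.08, and 4 were lower: Zbtb16 (-3.98), Nr3c1, which encodes the receptor itself, from 30.2 ± 2.66 to 6.00 ± 2.07 CPM, Klf9 from 1529 ± 25.1 to 783 ± 102 CPM, and Pdk4 by 0.70 ± 0.18, the last not called with library size alone. Cirbp, the 1 tested cold-induced gene, rose from 24.2 ± 1.98 to 81.7 ± 12.2 CPM. Of 10 heat shock genes not looked at before, 9 fell and none rose, where 2476 of all 7020 tested genes fell. With library size alone 5 of the 10 fell and 1 rose.

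Loss of tubule cells would make clock genes vary between tumour areas as tubule genes do, if tubule cells were their main source. The median SD over the tumour areas was 0.213 for 11 clock genes and 0.736 for 49 tubule genes, a ratio of 0.29. Under that condition, which was not tested, the ratio argues against that loss as the whole cause. Tissue taken at different times of day was examined with heat shock genes, which follow body temperature together with Per2, and a median under 0 was predicted. Their median log2 fold change was -0.43, although it was only -0.14 with library size alone. Hsph1 and Hsp90aa1 had already been seen to fall, and other differences between the groups could lower these genes too. The median therefore does not separate time of day from other causes, and time of day stays open. Times of collection are not given, and the genotype, the strain and the tumour itself stay open and untested.

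Many genes of families that nearly all cells express were at 0 or near it in all libraries: 125 of 377 (33.2%) held under 10 counts, and 102 held none, some of them members found in few tissues, such as Cox4i2 and Cox6b2. Near-identical copies elsewhere do not account for this, since 28.7% of 223 genes without a copy held under 10 counts (39.6% of 154 with a copy). Nor do overlapping genes, since 31.4% of 172 genes without an overlap did so (34.6% with one). The share was 44.7% among the 20% of genes with the smallest part of their exons in only 1 transcript and 14.5% among the 20% with the largest, a ratio of 3.09, and 1 of 13 genes with only 1 annotated transcript (7.69%) was affected against 34.1% of the others. A candidate explanation is that reads shared by several transcripts were left out of the counts, so that levels may depend on transcript structure, and whether the groups differ in it was not tested.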
